A study of Mus musculus with 18 samples.

How the data were processed

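RNA libraries of 18 samples from 5 male mouse embryonic stem cell lines were analysed, with 4 libraries each for MF, D12 and F4 and 3 each for D11 and G2. The deposited values are of the unit count, whole-gene read counts per sample, in a table of 43626 gene identifiers. According to the submitters' processing notes, reads were aligned with HISAT2 2.0.0.0, handled with SAMtools 1.1, counted with featureCounts 1.4.6-p2 and analysed with DESeq2 1.8.2, on mm10 and GRCm38.p3. The strand setting of the counting, the treatment of reads with several matches and the annotation release are not given in the sources used here. Identifiers were joined without version to GENCODE vM21 on GRCm38, which matched 42548 of them (97.53%). Unmatched identifiers held at most 0.2529% of the counts of a library.

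Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr by line, which left 15877, and libraries were scaled with TMM factors. All 18 libraries entered 1 fit with a mean per line and no covariate, and the comparisons were taken from robust quasi-likelihood F-tests, two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were D12, D11, F4 and G2 against MF, D12, F4 and G2 against D11, and G2 against F4. The SE of a log2 fold change was its size divided by the square root of F. Log2 CPM used a prior count of 2. Total counts lay between 14945027 and 19124187 per library, and the 10 most abundant genes held 4.852 to 6.907% of them. A level of 3 counts was taken as the floor of what a library can show. In simulated data with 100 genes changed at each size, the fit recovered 71 to 84% of those changed 2-fold and 95 to 100% of those changed 4-fold, with 2 to 13 false calls. The simulated counts were drawn independently around the MF means, and only genes with a mean of at least 1 CPM were changed. No difference between passages or clones was simulated, so these rates do not cover such structure among the real libraries.

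Chromosomes 1 to 19 and X were tested as sets with camera on log2 CPM at a correlation between genes of 0.01, and again with an estimated correlation, and adjusted over 80 tests. The 24 gene lists were written before the count files were opened. They were tested in the same way over 96 tests and with fry, and list members were also adjusted over the list alone. The X-linked minus autosomal expression of each library was compared by exact two-sided permutation of libraries, adjusted over 5 comparisons. Shared calls between lines were set beside unchanged groups simulated against shared MF libraries, and beside comparisons with the MF libraries split.

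The named genes followed a rule written before the files were opened. For each comparison with MF these were the 10 largest changes in each direction among called genes with a mean of at least 5 CPM in the higher line and no overlap between the libraries of the lines. For the other comparisons the 3 largest were taken, and for D12 against both MF and D11 the 5 largest. Predicted genes, pseudogenes and genes without a symbol were left out. A fixed set of genes of the MSL complex, X inactivation and pluripotency was always named, as were up to 4 members of each list and the Y-linked genes. Other called list members are named where a list is described.

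Alternatives were DESeq2 size factors, upper-quartile factors, the DESeq2 Wald test, limma-voom, no filter, a minimum mean of 5 CPM, glmTreat, passage as a covariate, a block by replicate name, each passage alone, only the lines compared, another prior count of 0.5, medians, and leaving out each library. Analyses without chromosomes 1 and 6, and without the passage 5 libraries of D11 and G2, were added after the data were seen. The smallest exact p of 4 against 3 libraries is 0.0286, and the planned analysis had stated a larger value by mistake. Exon-level analysis was not done because the deposited counts are per gene, so the deleted exons of D12 and the Drosophila sequence of F4 and G2 could not be examined.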

Results

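Polyadenylated RNA was sequenced from 5 lines of male mouse embryonic stem cells grown in medium with leukaemia inhibitory factor and inhibitors of the MEK and GSK3 kinases, which holds cells in the naive pluripotent state. MSL2 is the RING-finger subunit of the MSL complex, which acetylates histone H4. In Drosophila this complex raises the output of the single male X chromosome. MF was the parental line. D12 was an Msl2 knock-out and D11 carried wild-type Msl2 with an affinity tag. F4 carried the C-terminal domain of Drosophila MSL2 and G2 the Drosophila CXC domain together with the C-terminal domain, both with the same tag as D11. Against MF, F4 and G2 therefore combine tag and swap, while their comparisons with D11 have the tag on both sides. MF, D12 and F4 had 4 libraries each and D11 and G2 had 3 each, taken at passages 4 and 5. D11 and G2 had 1 library from passage 5. Total counts ranged from 14945027 to 19124187 per library and 15877 genes were tested. The labels do not say that the libraries of a line came from separate cultures, and each genotype is a single line, so p-values measure the spread between these libraries and not between clones. Log2 fold changes that carry a ± are given with their SE, and the others without it. Expression levels are in CPM, counts scaled to library size, as mean ± SD. Adjusted p-values come from the edgeR quasi-likelihood test unless another test is named.

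The targeted gene was examined first. Msl2 (ENSMUSG00000066415.4, chromosome 9, 101074101 to 101104800, GRCm38) was measured at 55.9 ± 6.53 CPM in MF (n = 4), 53.7 ± 4.43 in D11 (n = 3), 34.2 ± 1.92 in D12 (n = 4), 47.3 ± 3.91 in F4 (n = 4) and 44.2 ± 0.427 in G2 (n = 3). It was lower in D12 than in MF (log2 fold change -0.71 ± 0.09, adjusted p = 7.26e-05), and every D12 library lay below every MF library. The knock-out deletes exons 1 and 2 and the counts cover the whole gene, so transcripts from the remaining sequence are still counted. D11 did not differ from MF (adjusted p = 0.749). The values of F4 (-0.24 ± 0.09, adjusted p = 0.118) and G2 (-0.34 ± 0.10, adjusted p = 0.084) were not called, and G2 passed the threshold in the DESeq2 Wald test (adjusted p = 0.0225). Sequence from Drosophila is not part of the mouse gene and is not counted in F4 and G2. Kat8, the histone acetyltransferase of the complex, fell in D12 from 33.6 ± 1.19 to 26.8 ± 1.21 CPM (-0.32 ± 0.08, adjusted p = 0.0141), a call that was lost with no filter on low counts (adjusted p = 0.0810) and without D12 p5-2 (adjusted p = 0.0505). Msl1 and Msl3 were not called in any of the 4 lines against MF over all genes, while adjusted over the list alone Msl3 was higher in D12 and D11 and Msl2 lower in G2. The MSL complex list, with 2 of 4 members lower in D12, did not pass the camera set test there (adjusted p = 0.195) but was called lower by the fry set test (adjusted p = 0.00182). This list includes Msl2, the gene edited in D12, so its fry call there follows in part from the edit itself. It did not pass camera in D11 (0.392), F4 (0.721) or G2 (0.627), nor fry (adjusted p = 0.0665, 0.723 and 0.575). The related NSL complex, which shares KAT8, was not called as a list by camera (adjusted p = 0.718, 0.461, 0.568 and 0.721 in D12, D11, F4 and G2), and Kansl3, on chromosome 1, was its single called member, in D11 (0.56).

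**Figure D1:**
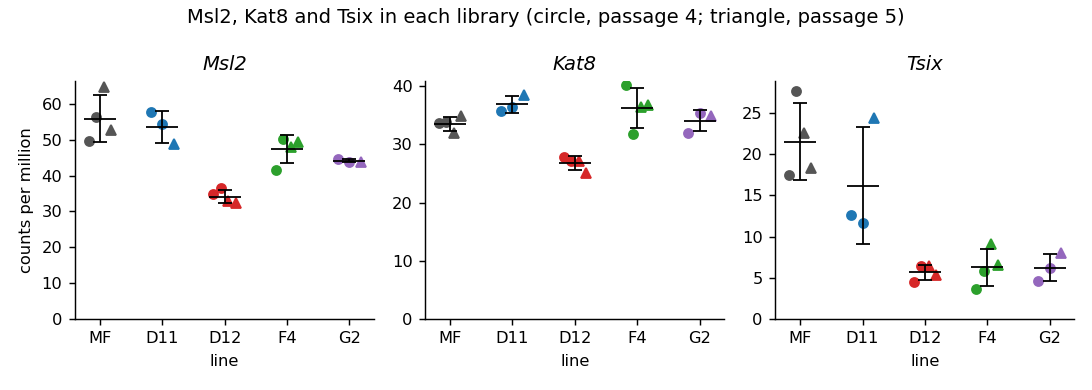
CPM (y axis, from 0) of Msl2, Kat8 and Tsix in each library of the 5 lines (x axis), with circles for passage 4, triangles for passage 5 and black bars for mean ± SD. The 4 D12 libraries lie below the 4 MF libraries for Msl2 (34.2 against 55.9 CPM on average), and Tsix averages 5.68 in D12, 6.26 in F4 and 6.24 in G2 against 21.5 in MF.

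Loss of Msl2 was assessed first by comparing D12 with the parental line. Acta2, smooth muscle actin, rose from 2.91 ± 2.83 to 24.3 ± 3.08 CPM (3.08 ± 0.78, adjusted p = 0.0124), and the T-box factor Eomes from 5.79 ± 1.45 to 33.1 ± 0.0148 CPM (2.52 ± 0.29, adjusted p = 2.67e-05). Rhox13, an X-linked homeobox gene, fell from 63.5 ± 13.2 to 6.36 ± 1.08 CPM (-3.31 ± 0.23, adjusted p = 2.97e-07), Dppa3, a maternal-effect gene, from 14.7 ± 8.31 to 1.05 ± 0.398 CPM (-3.79 ± 0.62, adjusted p = 0.000459), and Otx2, a homeobox gene of formative pluripotency, from 12.3 ± 2.01 to 1.16 ± 0.274 CPM (-3.4 ± 0.32, adjusted p = 4.78e-06). The other genes with the largest rises were Ptgs1 (3.70), Cd180 (3.26), Foxd1 (3.18), Rerg (3.02), Nt5e (2.54), Myl9 (2.40), Zyx (2.27) and Epha1 (2.25), of which Rerg, Zyx and Epha1 lie on chromosome 6. The other largest decreases were those of the imprinted RNA H19 (-4.00), Esx1 (-2.86), Stra8 (-2.81), Dmrt1 (-2.77), Mir9-3hg (-2.76), Usp17lb (-2.74) and Pet2 (-2.61). Stra8 and Dmrt1 act in germ cell development. In all, 2314 genes changed, 1163 higher and 1151 lower, and this balance depended on scaling, with 1032 higher and 1318 lower under upper-quartile factors. The 4 D12 values of Eomes lay closer together than counting noise (chi-square lower-tail p = 1.83e-06, where 0.129 so small are expected by chance among 70646 tests of genes and lines, looked at after the values were seen), and their SD was 0.483 CPM when scaled by library size alone, so the SD printed for it understates its spread. Of the 1163 higher genes, 328 lay on chromosome 6, and 771 genes rose and 1069 fell off chromosomes 1 and 6. Without 1 library the count ranged from 1516 (without MF p4-1) to 2052, and it was 3388 in passage 4 and 2275 in passage 5. Of 77 named genes called, 64 kept their call without any 1 library, Msl2 and Tsix among them, and 10 lost it without D12 p4-2.

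Among the 24 gene lists, 9 passed the camera set test in D12 against MF, and none of them did with an estimated correlation. Germline genes fell together, 12 of 18 (16 adjusted over the list alone), with Taf7l (-1.91), Mael (-1.76), Stk31 (-0.96) and Syce1 (-1.10) leading (median -0.87, set adjusted p = 1.2e-10, and adjusted p = 0.241 with an estimated correlation). Genes of the 2-cell-like state, a rare state of embryonic stem cells, fell in 10 of 21 cases (11 adjusted over the list alone), with a median of -1.90 (adjusted p = 1.16e-08, and 0.405 as the adjusted p with an estimated correlation). Arg2 (-2.28) and Zscan4d (-2.32) were among them. Members of the Usp17l, Zscan4, Tdpoz and Tcstv families have near-identical copies, and their counts are uncertain because the treatment of reads with several matches is not given in the sources used here. Primitive streak and mesoderm genes rose in 3 of 8 cases, also over the list alone, Eomes, Cdx1 (2.04) and Evx1 (2.03, on chromosome 6; set adjusted p = 0.0278, and adjusted p = 0.36 with an estimated correlation). Without members on chromosome 6 the streak call was lost (adjusted p = 0.0779). The fibroblast list, kept as a check for feeder cells, rose with Fbn1 (1.49), Acta2 and Thy1 (0.92), 3 of 10 members under either adjustment (adjusted p = 0.0488, and adjusted p = 0.241 with an estimated correlation). It lost its call with members on chromosome 6 left out of all lists (adjusted p = 0.0583). The adjustment runs over all lists, so this loss need not come from its own members. Glycolytic genes rose in 6 of 20 cases by both counts, among them Hk2 (1.00), Ldha (0.66), Gapdh (0.53) and Tpi1 (0.79). Hk2, Gapdh and Tpi1 lie on chromosome 6, which was raised in D12, and the set call (adjusted p = 0.00228, and adjusted p = 0.15 with an estimated correlation) was lost without members on that chromosome (adjusted p = 0.197). The amino acid and integrated stress response list rose in 5 of 20 cases by both counts, with Mthfd2 (0.74) and Asns (0.74) on chromosome 6 and Cth (0.88) and Atf4 (0.67) elsewhere (adjusted p = 0.0488, 0.617 as the adjusted p with an estimated correlation, and 0.245 without members on chromosome 6). The Hox list rose with 6 Hoxa genes of chromosome 6, led by Hoxa9 (3.12) and Hoxa10 (1.76), while Hoxb13 fell (-3.77). Over the list alone 6 rose and 2 fell (adjusted p = 0.0109, and adjusted p = 0.363 with an estimated correlation), and without chromosome 6 the direction turned and the call ended (adjusted p = 0.952). The X inactivation centre list fell with Tsix and Tsx (-1.55), 2 of 7, or 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.0193, and adjusted p = 0.346 with an estimated correlation). Y-linked genes fell in 2 of 7 cases, Kdm5d (-1.36) and Ddx3y (-0.64), and 4 adjusted over the list alone (adjusted p = 0.0114, and adjusted p = 0.405 with an estimated correlation).

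The fibroblast call was also lost with DESeq2 size factors (adjusted p = 0.0532) and with genes of at least 5 CPM (0.234), that of the stress response list with DESeq2 size factors (0.0532), and that of the Y-linked list with genes of at least 5 CPM (0.102). Fry did not call the stress response list (adjusted p = 0.0953). The other 15 lists did not pass camera in D12, with adjusted p from 0.0842 to 0.946, and of these fry called the MSL complex, formative (adjusted p = 0.0184) and neural (0.0104) lists lower, while the p53 targets passed camera with genes of at least 5 CPM (0.0370). Of the naive pluripotency genes, Tfcp2l1 (0.74), Stat3 (0.52), Klf5 and Tbx3 rose and Dppa3 and Klf2 (-0.55) fell, while Nanog (0.14), Pou5f1 (0.04), Sox2 (-0.13), Esrrb (0.23), Klf4 (0.23) and Zfp42 (-0.18) were not called. Imprinted genes moved both ways, 6 higher and 4 lower of 32, with Nnat (1.62), Plagl1 (1.21) and Peg3 (0.82) up and Slc38a4 (-1.44) down. In these 2 lists the median, the mean and the test did not share a sign. Formative genes fell in 3 of 11 cases, Otx2, Lef1 and Dnmt3a, and neural genes in 3 of 8, Sox21 (-2.13), Tubb3 and Nes. Primitive endoderm genes split into 1 higher (Hnf4a) and 3 lower (Pdgfra, Lamb1, Gata4) of 17, and trophoblast genes into 2 higher (Eomes, Tead4) and 3 lower (Esx1, Tfap2c, Gata3) of 12. Wnt targets gave 3 higher, Axin2, Cdx1 and Sp5 (2.32), and Lef1 lower. ERK targets gave Etv4 (1.03) and Fos higher, immediate early and heat shock genes Hsph1, Dnajb1 and Fos higher, extracellular matrix genes Vcl (0.87), Itga3 and Lgals1 higher and Lamb1 lower, and p53 targets Ei24 lower (-0.28). No member of the cholesterol synthesis or mitochondrially encoded lists was called.

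Set against D11, the tagged wild-type line, D12 differed in 5098 genes, 2154 higher and 2944 lower. Acta2 rose from 0.822 ± 1.24 to 24.3 ± 3.08 CPM (5.00 ± 1.03, adjusted p = 0.00137), followed by Foxd1 (4.78) and the ectonucleotidase Nt5e (4.67). Ddr2, a collagen receptor on chromosome 1, fell from 19.5 ± 7.39 to 0.904 ± 0.285 CPM (-4.42 ± 0.47, adjusted p = 4.24e-06), with Usp17la (-4.33) and Usp17lb (-4.32). Against both MF and D11, 1805 genes changed in D12 in 1 direction, 854 higher and 951 lower, and 1428 of these lay off chromosomes 1 and 6. Of the 854 rises, 268 lay on chromosome 6. Only 3 genes were called in opposite directions, but both comparisons use the same D12 libraries, which favours agreement in direction. Ranked by the smaller of the changes in the 2 comparisons, Ptgs1, Cd180, Foxd1, Acta2 and Rerg came first among the rises and Dppa3, H19, Rhox13, Otx2 and Esx1 among the decreases. The count against D11 fell to 3299 without D11 p4-2, was 6574 without the passage 5 library of D11, and was 7518 in passage 4 and 3664 in passage 5.

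The comparison of D11 with MF shows what accompanied the tagged wild-type allele. Tgfbi, a secreted matrix protein, rose from 1.08 ± 0.391 to 8.33 ± 4.95 CPM (2.96 ± 0.45, adjusted p = 0.00287) and Fn1, fibronectin, on chromosome 1, from 390.4 ± 33.5 to 873 ± 321 CPM (1.16 ± 0.20, adjusted p = 0.00371). Crmp1 fell from 15.4 ± 5.89 to 3.4 ± 3.48 CPM (-2.22 ± 0.47, adjusted p = 0.00972). The other largest rises were Trpa1 (2.55), Ddr2 (2.32), Naalad2 (2.24), Tns1 (2.24), Grk3 (2.02), Ttc21b (1.92), Atp2b4 (1.8), Ankrd44 (1.8) and Hmgn3 (1.75), and Trpa1, Ddr2, Tns1, Atp2b4 and Ankrd44 lie on chromosome 1. The other largest decreases were Enpp3 (-1.71), Eif2s3y (-1.55), Pax6 (-1.49), Nlrc4 (-1.46), Esam (-1.46), Mid1 (-1.46), Vsig2 (-1.41), Kdm5d (-1.40) and Uba1y (-1.38). In all 1175 genes changed, 903 higher and 272 lower, and 401 of the higher genes, 44.4%, lay on chromosome 1. The passage 5 library, p5-2, stood apart from the passage 4 libraries and set the count, which was 4321 without it and fell to 134 without D11 p4-2, 219 without D11 p4-1 and 324 in a fit of D11 and MF alone. Within passage 4 the count was 5688 and within passage 5, with 1 D11 library, it was 57, and of 55 named genes called 15 kept their call without any 1 library.

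Of the lists, 7 passed in D11 against MF and none with an estimated correlation. Y-linked genes fell in 3 of 7 cases, Eif2s3y, Kdm5d and Uba1y (4 adjusted over the list alone; median -1.22, adjusted p = 0.00213, and adjusted p = 0.36 with an estimated correlation). Formative and primed genes fell with Dnmt3b (-1.03), 1 of 11, or 5 adjusted over the list alone (adjusted p = 0.00125, and adjusted p = 0.241 with an estimated correlation). Neural genes fell with Pax6 and Tubb3 (-0.63), 2 of 8, or 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.0488, and adjusted p = 0.241 with an estimated correlation). Of the 11 Wnt targets Axin2 fell (-1.0), with 4 adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.36 with an estimated correlation), and of 14 ERK targets Etv5 fell (-0.49), with 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.00213, and adjusted p = 0.448 with an estimated correlation). The 2-cell-like list rose with Arg2 (1.47), Usp17la and Usp17lb, 3 of 21 (8 adjusted over the list alone; adjusted p = 3.26e-05, and adjusted p = 0.575 with an estimated correlation). Germline genes rose in 4 of 18 cases, Asz1 (1.69), Sohlh2 (1.46), Slc25a31 and Syce1 (6 adjusted over the list alone; adjusted p = 0.00312, and adjusted p = 0.571 with an estimated correlation). The neural call was lost with DESeq2 size factors (adjusted p = 0.0532) and the Wnt call with genes of at least 5 CPM (0.1003). Fry did not call the 2-cell-like (adjusted p = 0.130), germline (0.0957) or ERK (0.0999) lists. The other 17 lists did not pass, with adjusted p from 0.288 to 0.967. Among the naive genes Nanog rose (0.57 ± 0.17, adjusted p = 0.0423), a call lost with DESeq2 size factors (adjusted p = 0.0526) and without either D11 p4 library or any 1 MF library. So did Tfcp2l1 (0.70), Nr5a2 and Prdm14, which lie on chromosome 1. Imprinted genes gave 1 higher, Grb10, and 5 lower, led by Mest (-1.27). Called members of other lists were Afp, Gsc, Fn1, Btg2, Pmaip1, Ldha (0.46), Hsd17b7, Phgdh (0.77), Hspa1a, Hoxc4 and Nid1 higher, and Pdk1 (-0.80), Slc2a1, Bnip3 and Hoxa10 (-1.83) lower. No trophoblast, X inactivation centre or mitochondrially encoded gene was called. The median, mean and test did not share a sign for the fibroblast, imprinted, cholesterol, immediate early and extracellular matrix lists.

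**Figure D2:**
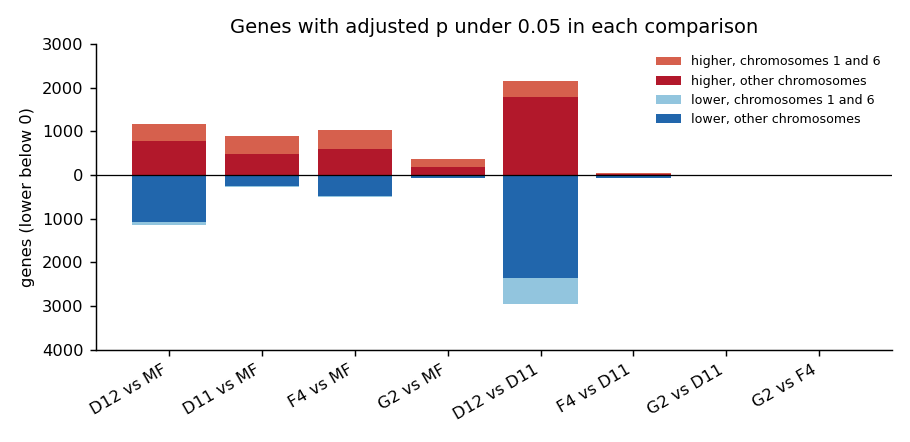
Number of genes with an adjusted p under 0.05 (y axis, higher genes above 0 and lower genes below it) in each of the 8 comparisons (x axis), with lighter parts for genes on chromosomes 1 and 6. D12 against D11 gave 5098 genes and D12 against MF 2314, while F4 against D11 gave 101, G2 against D11 7 and G2 against F4 1.

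Replacement of the C-terminal domain, together with the tag, was assessed in F4 against MF. All 21 measured genes of the 2-cell-like list rose. The single-copy gene Arg2, an arginase, rose from 1.23 ± 0.334 to 10.9 ± 5.54 CPM (3.15 ± 0.36, adjusted p = 0.000138), and Zscan4c from 3.90 ± 1.36 to 37.7 ± 26.3 CPM (3.28 ± 0.46, adjusted p = 0.000405). The largest rises were Tcstv3 (3.87), Pramef25 (3.86), Lmx1a (3.68), Zfp352 (3.53), Tcstv1 (3.52), H2-M10.4 (3.50), Trim43a (3.39), Chit1 (3.38), Usp17lc (3.33) and Usp17ld (3.32). Lmx1a and Chit1 lie on chromosome 1, and the counts of Pramef25, Trim43a and the Tcstv and Usp17l families are uncertain because of near-identical copies. The decreases were led by Gng3 (-1.89), a G-protein subunit, and by Tsix, the antisense regulator of Xist (ENSMUSG00000085715.1, chromosome X, 103431517 to 103484957), from 21.5 ± 4.69 to 6.26 ± 2.25 CPM (-1.79 ± 0.27, adjusted p = 0.000532). They were followed by Dnajc22 (-1.70), Xlr5a (-1.64), Mir9-3hg (-1.55), Pnma5 (-1.55), Mmp14 (-1.55), Dnajc6 (-1.42), Firre (-1.32) and Arhgap45 (-1.30). Firre is an X-linked long non-coding RNA. In all 1517 genes changed, 1022 higher and 495 lower, and 387 of the higher genes, 37.9%, lay on chromosome 1. The count was 3389 in passage 4 and 873 in passage 5, and fell to 835 without MF p4-2 and 837 without F4 p4-1. Of 67 named genes called, 48 kept their call without any 1 library, Tsix and Firre among them.

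In F4, 9 lists passed and none with an estimated correlation. The 2-cell-like list had a median of 3.16 with 21 members higher under either adjustment, all genes or adjusted over the list alone (adjusted p = 3.19e-23, and adjusted p = 0.241 with an estimated correlation). Germline genes rose in 6 of 18 cases, led by Asz1 (1.41), Slc25a31 (1.05) and Syce1 (0.78), and in 10 adjusted over the list alone (adjusted p = 7.75e-06, and adjusted p = 0.369 with an estimated correlation). Trophoblast genes rose in 4 of 12 cases by both counts, Plac1 (2.94), Rhox9 (1.45), Rhox6 and Gata3 (adjusted p = 0.0109, and adjusted p = 0.392 with an estimated correlation). Immediate early and heat shock genes rose in 4 of 12 cases by both counts, Hspa1a (1.89), Fos (1.36), Jun and Atf3 (adjusted p = 0.0342, and adjusted p = 0.575 with an estimated correlation). Neural genes fell in 3 of 8 cases, Pax6 (-1.23), Sox1 (-1.02) and Ncam1, and in 4 adjusted over the list alone (adjusted p = 0.0171, and adjusted p = 0.241 with an estimated correlation). The X inactivation centre list fell with Tsix and Rlim (-0.31), 2 of 7, or 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.0238, and adjusted p = 0.36 with an estimated correlation). Y-linked genes fell with Kdm5d, Uty and Uba1y while Usp9y rose (1.84), or 1 higher and 6 lower adjusted over the list alone (adjusted p = 0.00781, and adjusted p = 0.392 with an estimated correlation). Formative genes fell with Dnmt3b (-0.59), 3 adjusted over the list alone, and Wnt targets with Tcf7 (-0.50), 1 adjusted over the list alone, each at an adjusted p of 0.0488, with adjusted p = 0.369 and 0.405 with an estimated correlation. With members on chromosome 1 left out of all lists, these 2 calls were lost (adjusted p = 0.0583 for each), as was that of the immediate early list (adjusted p = 0.0792). The adjustment runs over all lists, so these losses need not come from members of the same lists. With genes of at least 5 CPM these 3 calls were lost as well (adjusted p = 0.136, 0.102 and 0.494), and with DESeq2 size factors those of the formative and Wnt lists (0.0532 for each), which fry did not call either (adjusted p = 0.0572 and 0.0672). The other 15 lists did not pass, with adjusted p from 0.0924 to 0.961. Their called members were the p53 targets Phlda3 (0.92), Btg2, Pmaip1 and Plk2, the imprinted genes H19, Igf2, Phlda2 and Cdkn1c (1.19), and Tbx3, Afp, Dab2, Ldha and Phgdh (0.90) higher, and Gnas, Peg3, Mest (-0.80), Impact, Chac1, Slc7a5, Srebf2, Spred2, Itgb1 and the Hox genes Hoxa10 (-2.31), Hoxa9 and Hoxa7 lower. No primitive streak, fibroblast or mitochondrially encoded gene was called. The median, mean and test did not share a sign for the naive, fibroblast, imprinted and ERK lists.

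**Figure D3:**
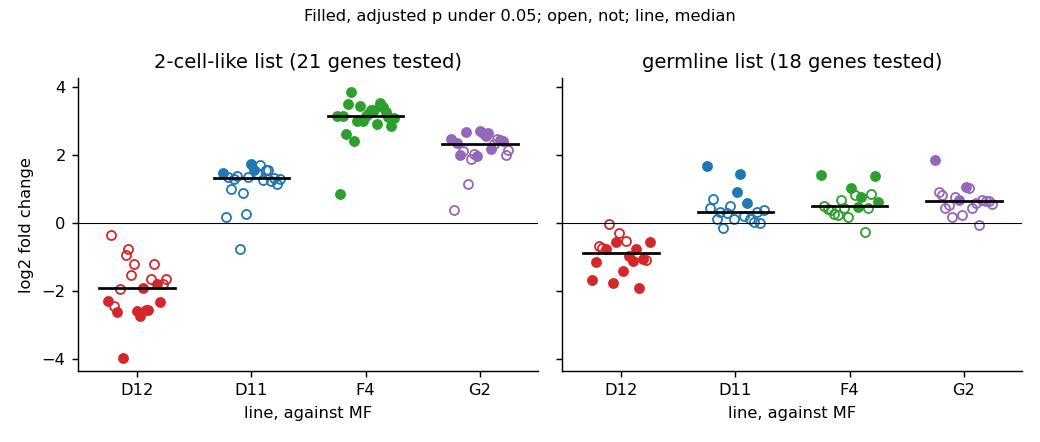
Log2 fold change against MF (y axis) of each tested gene of the 2-cell-like list (21 genes) and the germline list (18 genes) in D12, D11, F4 and G2 (x axis), filled where the adjusted p was under 0.05, with a black line at the median. The 2-cell-like medians were -1.90 in D12, 1.32 in D11, 3.16 in F4 and 2.33 in G2, and those of the germline list -0.87, 0.33, 0.50 and 0.64.

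Replacement of both the CXC and the C-terminal domain, together with the tag, was assessed in G2 against MF. Arg2 rose from 1.23 ± 0.334 to 6.76 ± 2.34 CPM (2.46 ± 0.38, adjusted p = 0.00467) and Lmx1a, a LIM homeobox gene on chromosome 1, from 0.813 ± 0.314 to 5.48 ± 2.15 CPM (2.76 ± 0.46, adjusted p = 0.00576). Tsix fell from 21.5 ± 4.69 to 6.24 ± 1.70 CPM (-1.79 ± 0.30, adjusted p = 0.00576) and Firre from 6.41 ± 1.53 to 2.35 ± 0.405 CPM (-1.44 ± 0.24, adjusted p = 0.00576). The other largest rises were Usp17la (2.72), Usp17ld (2.65), Usp17lb (2.64), Chit1 (2.64), Usp17lc (2.56), Zscan4c (2.45), Zscan4d (2.42) and Ddr2 (2.37), and the other largest decreases Gng3 (-1.57), Pnma5 (-1.48), Dnajc6 (-1.38), Mir9-3hg (-1.38), Mmp14 (-1.12), Prss41 (-1.02), Glipr2 (-0.84) and Spata24 (-0.83). In all 434 genes changed, 370 higher and 64 lower, with 164 of the higher genes, 44.3%, on chromosome 1. The passage 5 library of G2, p5-1, stood apart, and the count was 1192 without it, 62 without G2 p4-1, 2 without G2 p4-2 and 211 in a fit of G2 and MF alone. It was 2595 within passage 4 and 41 within passage 5, which has 1 G2 library, and each of the 30 named genes called lost its call without G2 p4-2.

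In G2, 4 lists passed and none with an estimated correlation, for each of which the adjusted p was then 0.241. The 2-cell-like list rose in 12 of 21 cases (19 adjusted over the list alone), with a median of 2.33 (adjusted p = 1.52e-21). Germline genes rose in 3 of 18 cases, Asz1 (1.85), Slc25a31 (1.06) and Mov10l1, and in 11 adjusted over the list alone (adjusted p = 4.84e-09). The X inactivation centre list fell with Tsix and Rlim (-0.33), 2 of 7 by both counts (adjusted p = 0.00899). The neural list was lower with no called member, or 1 adjusted over the list alone (median -0.28, adjusted p = 0.0316). The other 20 lists did not pass, with adjusted p from 0.0690 to 0.961, and their called members were Usp9y (2.06), Afp, Pmaip1, Ldha (0.50), Phgdh (0.66) and Hspa1a (1.94), all higher. No naive, formative, primitive streak, trophoblast, fibroblast, imprinted, mitochondrially encoded, cholesterol, Wnt, ERK, Hox or extracellular matrix gene was called over all genes, while 4 imprinted genes and 1 Hox gene were lower adjusted over the list alone. The median, mean and test did not share a sign for the imprinted, Y-linked, cholesterol, ERK and Hox lists.

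The swap lines were then compared with the tagged wild-type line, and with each other. Firre (ENSMUSG00000085396.3, chromosome X, 50555744 to 50635321) was lower in both, at 2.56 ± 0.299 CPM in F4 and 2.35 ± 0.405 in G2 against 11 ± 2.82 in D11 (log2 fold change -2.10 ± 0.23, adjusted p = 0.000217 in F4, and -2.22 ± 0.25, adjusted p = 0.000518 in G2), and the call held without any 1 library in both comparisons but not in a fit of only the lines compared. D11 itself was above MF for Firre (log2 fold change 0.78, adjusted p = 0.0362), a value looked up after the others were seen. In F4 against D11, Lmx1a (1.93), Arg2 (1.68) and Nat8f2 (1.54) were higher and Fignl2 (-1.69) and the desmosomal gene Dsp (-1.54) lower. In G2 against D11, Thoc5, a subunit of the RNA export complex THO, was 129 ± 4.44 against 65.7 ± 8.45 CPM (0.97 ± 0.10, adjusted p = 0.000272), Col6a5 was higher (1.46), and Dnajc6 (-1.43) and Zfp185 (-1.32) were lower. For Thoc5 it was D11 that stood apart, at 58.8 to 75.2 CPM per library. Every library of the other lines, MF included, was at 106 CPM or more. Between G2 and F4 the single gene called was the kinase Nek6, at 35.1 ± 2.18 against 16.6 ± 2.35 CPM (1.08 ± 0.11, adjusted p = 0.000125). Here F4 stood apart, at 13.7 to 18.9 CPM per library, against 31.6 CPM or more in every library of the other lines. In all, 101 genes differed between F4 and D11, 37 higher and 64 lower, 7 between G2 and D11, 2 higher and 5 lower, and 1 between G2 and F4. In fits of only the lines compared, edgeR called 0 genes in each of these 3 comparisons, Firre, Thoc5 and Nek6 included, beside 3113, 1603 and 576 genes at an unadjusted p under 0.05 in the fit of all lines and 576, 125 and 1 called by the DESeq2 Wald test. These low counts do not show that the lines were alike. Within passage 4, with 2 libraries per line, the counts were 4837, 1710 and 560, without D11 p5-2 they were 4359 for F4 and 1537 for G2 against D11, and in passage 5 they were 11, 10 and 3. In the other direction, the count for F4 against D11 was 3 without either D11 p4 library, 5 without F4 p4-1 and 6 without F4 p4-2, and that for G2 against D11 was 2 without either D11 p4 library.

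Fold changes were next averaged by chromosome. Genes of chromosome 1 were higher than in MF in each of the 3 lines with a tagged allele. Their median log2 fold change over 997 genes was 0.51 in D11, 0.45 in F4 and 0.40 in G2 (camera adjusted p = 7e-34, 1.69e-39 and 1.67e-37, and adjusted p = 0.0149, 0.0128 and 0.0128 with an estimated correlation). In D12 the 715 genes of chromosome 6 had a median of 0.43 (adjusted p = 1.82e-27, and adjusted p = 1.91e-09 with an estimated correlation). On the linear scale these medians were 1.42, 1.36, 1.32 and 1.35 times MF. The 20 Mb windows along chromosome 1 ran from 0.35 to 0.65 and those along chromosome 6 from 0.30 to 0.57. By library, the chromosome 1 median over MF was 0.55 and 0.60 in the passage 4 libraries of D11 and 0.33 in p5-2, between 0.40 and 0.52 in F4, and 0.49 in both passage 4 libraries of G2 and 0.17 in p5-1, while the highest MF library was at 0.0242. That of chromosome 6 lay between 0.41 and 0.44 in the 4 D12 libraries. The other 17 autosomes had medians between -0.07 and 0.08 in all 4 comparisons, and chromosome 17 passed the test in G2 at -0.06 (adjusted p = 0.0165, and adjusted p = 0.123 with an estimated correlation). Chromosome 2 in D11, with a median of -0.01, passed only with an estimated correlation (adjusted p = 0.0205, against 0.502 at the fixed correlation).

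**Figure D4:**
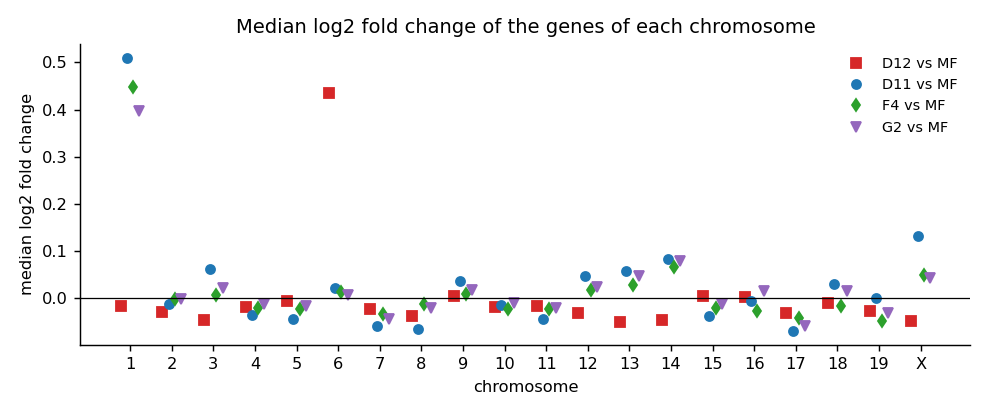
Median log2 fold change against MF (y axis) of the tested genes of chromosomes 1 to 19 and X (x axis) in D12, D11, F4 and G2. Chromosome 1 lies at 0.51, 0.45 and 0.40 in D11, F4 and G2 and chromosome 6 at 0.43 in D12, while the other autosomes lie between -0.07 and 0.08.

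Because the MSL complex acts on the X chromosome in Drosophila, expression of X-linked genes was set against that of autosomal genes within each library, as the mean log2 CPM of 696 X-linked genes minus that of 15035 autosomal genes. It was -0.91 ± 0.03 in MF (SD, n = 4), -1.09 ± 0.03 in D12 (n = 4), -0.75 ± 0.07 in D11 (n = 3), -0.87 ± 0.05 in F4 (n = 4) and -0.84 ± 0.15 in G2 (n = 3). D12 was lower than MF by -0.18 in 4 of 4 libraries and D11 higher by 0.15 in 3 of 3, each with an exact two-sided permutation p of 0.0286, the smallest these designs allow, and 0.0715 adjusted over the 5 comparisons. Neither therefore passed the correction. F4 (0.04, exact p = 0.171) and G2 (0.07, exact p = 0.343) did not pass either, nor did G2 against F4 (0.03, exact p = 0.800). Without chromosome 1 among the autosomes the value of F4 was 0.07 (exact p = 0.0857), and without G2 p5-1 that of G2 was 0.16 (exact p = 0.0667, the smallest that design allows) and that of G2 against F4 0.11 (exact p = 0.0667). Among genes of at least 5 CPM the difference was -0.11 in D12 (exact p = 0.0286), 0.07 in D11 (exact p = 0.0857), -0.04 in F4 (exact p = 0.143) and -0.01 in G2 (exact p = 0.943). Among genes of at least 20 CPM it was -0.04 in D12 (exact p = 0.0857), 0.02 in D11 (exact p = 0.314), -0.06 in F4 (exact p = 0.0571) and -0.04 in G2 (exact p = 0.143). Within passage 4 it was -0.19 in D12, 0.18 in D11, 0.02 in F4 and 0.14 in G2, and within passage 5 -0.17, 0.09, 0.07 and -0.09, where 2 libraries or fewer a line cannot reach an exact p under 0.333. G2 against F4 was 0.13 within passage 4 and -0.16 within passage 5. As a set, X-linked genes were not called by camera in D12 (median -0.05, adjusted p = 0.192), D11 (0.13, 0.108), F4 (0.05, 0.858) or G2 (0.04, 0.628). In D12, 98 X-linked genes fell and 31 rose, Rhox13 and Esx1 among the former. Tsix fell in D12 from 21.5 to 5.68 ± 0.914 CPM (-1.92 ± 0.27, adjusted p = 0.000125), as in F4 and G2, and was 16.2 ± 7.12 CPM in D11 (adjusted p = 0.376). The passage 4 libraries of D11, at 12.6 and 11.6 CPM, lay below every MF library, the lowest at 17.4, while p5-2 was at 24.4. Xist stayed at a mean of 0.675 CPM or lower in every line and was not called against MF over all genes. Adjusted over the list alone, Xist was higher in D12 and F4. In G2 it was 0.552 against 0.138 CPM in MF (adjusted p = 0.269). The MF libraries held 1 to 3 counts of Xist, at or below the floor, so the size of these differences is uncertain. Whether counting used the strand is not given in the sources used here, so reads of Tsix and Xist, which overlap on opposite strands, cannot be told apart with certainty.

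**Figure D5:**
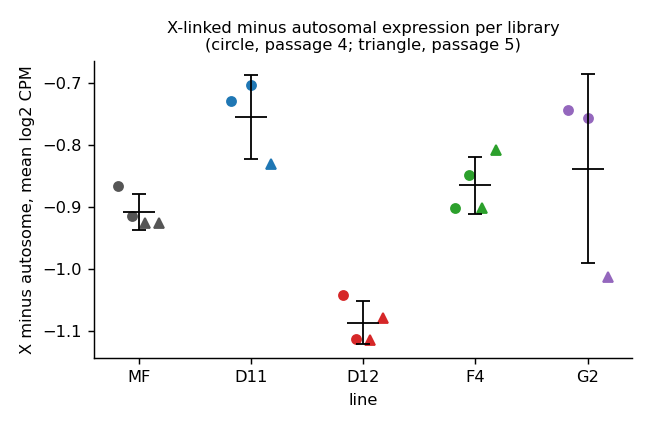
Mean log2 CPM of X-linked genes minus that of autosomal genes (y axis) in each library of the 5 lines (x axis), with circles for passage 4, triangles for passage 5 and black bars for mean ± SD. The D12 libraries lie between -1.11 and -1.04, below the MF libraries between -0.93 and -0.87, and G2 p5-1 lies at -1.01, apart from the other G2 libraries at -0.74 and -0.76.

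The changes against MF were compared between lines. F4 and G2 shared 393 calls in 1 direction and none in opposite directions, D11 and F4 shared 535 with 2 opposite, and D11 and G2 239 with 2 opposite. Off chromosomes 1 and 6 the shared calls were 222, 268 and 96, with 0, 2 and 2 opposite. Counts that involve G2 rest on its 434 calls, which fell to 2 without G2 p4-2 and to 62 without G2 p4-1. The correlations of log2 fold change across genes were 0.860, 0.655 and 0.706, and 0.851, 0.631 and 0.684 off those chromosomes. Unchanged groups simulated against the same MF libraries gave 0 shared calls and correlations of 0.461, 0.462 and 0.429. Independent lists of these sizes would share 23.8 higher and 2 lower genes for F4 and G2, 58.1 and 8.5 for D11 and F4, and 21 and 1.1 for D11 and G2. The covariances were 0.210, 0.178 and 0.158 against simulated values of 0.0301, 0.0301 and 0.0302. With the MF libraries split between the 2 comparisons, the correlations were 0.650, 0.493 and 0.5, with 41.5, 72.3 and 7.5 shared calls on average over 3 splits. The covariances with split MF libraries were 0.184, 0.152 and 0.131. With only 2 MF libraries per comparison fewer genes can be called, so these counts do not measure the effect of sharing MF alone. D12 went the other way more often than not. It shared 92 calls with D11 against 156 in opposite directions, 113 with F4 against 242 and 41 with G2 against 93, and off chromosomes 1 and 6 67 against 112, 87 against 184 and 31 against 67. The correlations were -0.217, -0.330 and -0.261 against simulated values of 0.463, 0.498 and 0.461, with covariances of -0.0644, -0.107 and -0.0695 against 0.0300, 0.0300 and 0.0301, and -0.288, -0.380 and -0.330 with split MF libraries, where 9.2, 27.7 and 5.7 calls were shared on average. Of the calls shared with D12, 69 were higher and 23 lower for D11, 58 and 55 for F4, and 16 and 25 for G2. Independent lists would share 66.1 higher and 19.7 lower genes with D11, 74.9 and 35.9 with F4 and 27.1 and 4.6 with G2. Shared decreases thus exceeded that number with F4 and G2, while shared rises fell below it. All these comparisons share the MF libraries. Genes are not independent replicates, and part of any excess may come from effects common to editing, to the tag or to the raised chromosome 1. The 2-cell-like list was lower in D12, with 10 of 21 members called, and higher in D11, F4 and G2, the tagged wild-type line included (median 1.32 in D11). None of these list calls held in camera with an estimated correlation, where the adjusted p was 0.405 in D12, 0.575 in D11 and 0.241 in F4 and G2. Tsix, Firre, Pnma5, Dnajc6 and Mir9-3hg fell in D12, F4 and G2. For D12, Firre (-1.48), Pnma5 (-1.59) and Dnajc6 (-2.60) were chosen after their values were seen.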

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

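The tests of an extra copy, of scaling and of mislabelled libraries were chosen after the results were seen. Mislabelling was tested in 3 versions. The first, with Firre, Thoc5 and Nek6, placed D11 p5-2 and G2 p5-1 with their own lines and was dropped because these genes had been chosen with both libraries included, the second took the share of all separating genes, and the third took 10 marker genes with bounds fixed before it was run. MF and D12 were set apart from the other lines, with a criterion on chromosome 1, after the third was seen. Its lowest count met the bound for mislabelling, and the explanation was left open only after counts as low against MF were seen. A library far from the others of its line was found in 12 of 285 groups of libraries, and chance marks about 1 in 20. This screen covered MF, D12 and F4, with 4 libraries each, and not D11 and G2, with 3 each. D12 p4-2 had a high share of mitochondrial counts (5.17%), a high share in the 10 most abundant genes (6.91%), high H19 (1.70 CPM) and low Ttc21b (3.88 CPM). D12 p5-1 was high for Esrrb (718 CPM) and Trim43a (0.247 CPM). MF p4-1 was high for Otx2 (15.3 CPM) and Msl3 (8.57 CPM), and MF p5-1 for Zfp185 (32.4 CPM). F4 p4-2 was high for Dnajc6 (18.2 CPM) and Xist (1.56 CPM), and F4 p5-2 was low for Mmp14 (6.25 CPM). The change against MF differed between passages 4 and 5, by a test of the interaction in edgeR, for 612 genes in D12 and 760 in F4, and for 1797 in D11 and 700 in G2, where a single passage 5 library cannot be told apart from passage.

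The first pattern weighed was the rise of chromosome 1 in D11, F4 and G2 and of chromosome 6 in D12. An extra copy of the chromosome in part of the cells would raise every stretch of it, and the lowest median of any 20 Mb window was 0.303. This is consistent with an extra copy, which RNA counts alone do not establish. Scaling between libraries would move other autosomes as well, and the largest median among them was 0.0845 from 0, so scaling was excluded by the criterion set. The TMM factors themselves hold most genes near 0, so this criterion was easily met. The values show that the raised chromosome moved apart from the other autosomes, which a single factor per library cannot produce. Genes matched for GC content and length had a median of at most 0.0274, which excluded these features.

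The second pattern was the distance of the passage 5 libraries of D11 and G2 from the passage 4 libraries, which 1 passage 5 library per line cannot separate from passage. Fewer cells with the gain of chromosome 1 stayed open. Other raised genes would then keep the same share of their excess as chromosome 1. They kept 0.743 against 0.489 in D11, a difference of 0.254 (95% interval 0.087 to 0.452). In G2 they kept 0.432 against 0.291, a difference of 0.141 (0.054 to 0.27). These intervals resample genes as if independent, with 1 passage 5 library per line, so they leave out the spread between libraries. The criterion, written beforehand, asked for both intervals wholly within or wholly outside a fixed distance from 0, and neither was met. A mislabelled MF or D12 library was excluded by the criterion on chromosome 1, whose median was 0.33 in D11 p5-2 and 0.166 in G2 p5-1 against at most 0.0242 in the MF and D12 libraries. Over all genes separating the passage 4 libraries, D11 p5-2 lay nearer its own line for 39.7% against MF and 56.5% against D12. For G2 p5-1 these shares were 44.3 and 52.8%, so the exclusion rests on chromosome 1 alone. A mislabelled library of D11, F4 or G2 stayed open: of 10 marker genes chosen without both libraries, D11 p5-2 lay on its own side for 0 against F4, 2 against G2, 0 against MF and 9 against D12, and G2 p5-1 for 1 against F4, 7 against D11, 1 against MF and 3 against D12, so that low counts arose against the excluded MF as well and do not support a swap, while over all genes separating the passage 4 libraries D11 p5-2 lay nearer its own line for 44.6% against F4 and 38.1% against G2 and G2 p5-1 for 81.5% against F4 and 69.9% against D11. The measures do not single out these libraries cleanly, since the F4 passage 5 libraries lay on their own side for only 5 of 10 markers against D11 and 4 against G2, and nearer their own line than G2 for 16.6 and 13.7% of genes, and Thoc5 (75.2 CPM in D11 p5-2) and Nek6 (37.3 CPM in G2 p5-1), which lie with their own lines, were chosen with these libraries included.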

How the results depend on the processing

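Counts of genes are given in the order of the comparisons named. The cause of each difference was not tested unless fewer genes or libraries by construction show it. With glmTreat against a log2 change of 1, D12, D11, F4 and G2 against MF gave 65, 0, 145 and 0 genes, D12, F4 and G2 against D11 573, 0 and 0, and G2 against F4 0, beside 3871 (D11), 2283 (G2), 3113, 1603 and 576 genes at an unadjusted p under 0.05 in the edgeR fit. The DESeq2 Wald test gave 1765 for D11 and 750 for G2 against MF, and 576 for F4 and 125 for G2 against D11. Limma-voom gave 54 for F4 against D11. With a minimum of 5 CPM, F4 and G2 against MF gave 916 and 227 and F4 against D11 39, with fewer genes tested. With passage as a covariate G2 against MF gave 691, F4 against D11 447 and G2 against D11 53. Libraries of 1 replicate name share a passage and a number, with correlations from -0.148 to 0.545 that are not all above 0.1, so they were not treated as pairs, and a block by name, which takes up passage as well, gave 328 for F4 and 19 for G2 against D11. Passage 4 alone gave 5688, 3389 and 2595 for D11, F4 and G2 against MF, 4837 and 1710 for F4 and G2 against D11 and 560 for G2 against F4. Passage 5 alone gave 57, 873 and 41, then 11 for F4 against D11 and 3 for G2 against F4, with lone libraries assumed to vary like the others. In analyses added after the data were seen, genes off chromosomes 1 and 6 gave 465, 894 and 194 for D11, F4 and G2 against MF. Without D11 p5-2 and G2 p5-1, D11 and G2 against MF gave 5308 and 1988, F4 and G2 against D11 5393 and 537, and G2 against F4 3. With only the lines compared, D11 and G2 against MF gave 324 and 211, and F4 against D11, G2 against D11 and G2 against F4 gave 0, 0 and 0.

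Without 1 library the counts ran from 1516 to 2052 for D12, 134 to 4321 for D11, 835 to 1404 for F4 and 2 to 1192 for G2 against MF, 3299 to 6574 for D12, 3 to 4359 for F4 and 2 to 1537 for G2 against D11, 1 to 2 for G2 against F4, and 1275 to 1934 for D12 against both. X minus autosome for D12 was -0.0447 with genes of at least 20 CPM, -0.19 in passage 4, -0.17 in passage 5 and -0.18 with the block, and -0.107 with at least 5 CPM, where it kept its exact p of 0.0286. Without the autosomes that shifted it was -0.16 in D12, 0.18 in D11, 0.0746 in F4 and 0.0947 in G2. For D11 it was 0.15 with medians, 0.0683 with at least 5 CPM, 0.0239 with at least 20 CPM, 0.18 in passage 4, 0.093 in passage 5 and 0.15 with the block. Without 1 library it ran from -0.19 to -0.16 in D12, 0.13 to 0.19 in D11, 0.02 to 0.06 in F4, 0.02 to 0.16 in G2 and -0.02 to 0.11 for G2 against F4. All 7 such values for D11 lost the threshold, which the smaller design cannot reach. Uncalled values of X minus autosome changed sign in 9 of 77 cases and those of named genes in 18 of 3567. The former were F4 with at least 5 CPM (-0.0379) and 20 CPM (-0.0575), G2 with at least 5 CPM (-0.0085), 20 CPM (-0.0421) and in passage 5 (-0.0875), and G2 against F4 with medians (-0.0375), in passage 5 (-0.157) and without G2 p4-1 (-0.0203) or p4-2 (-0.0136).

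With an estimated correlation 0 lists were called in any line, where camera at 0.01 called 9, 7, 9 and 4 and fry 11, 4, 7 and 4 in D12, D11, F4 and G2. With DESeq2 size factors 5 list calls were lost, each at an adjusted p of 0.0532: fibroblast and stress response in D12, neural in D11, and formative and Wnt in F4. With at least 5 CPM 6 were lost: fibroblast (0.234) and Y-linked (0.102) in D12, Wnt in D11 (0.1003), and formative (0.136), Wnt (0.102) and immediate early (0.494) in F4, and p53 targets in D12 were gained (0.0370). With the block 3 were lost, stress response in D12 (0.0666) and formative and immediate early in F4 (0.0706 each), and 2 gained, p53 targets in D12 (0.0198) and stress response in G2 (0.0417). The Hox list of D12 reversed without chromosome 6 (adjusted p = 0.952), whose 6 raised members are all Hoxa genes. With MF split, which leaves 2 MF libraries per comparison, shared calls were 9.2 (D12 and D11), 27.7 (D12 and F4), 5.7 (D12 and G2), 72.3 (D11 and F4), 7.5 (D11 and G2) and 41.5 (F4 and G2). With an absolute log2 fold change of at least 1 they were 20, 27, 12, 148, 92 and 192. Other scalings moved the median of all genes by -0.0311 to 0.0198.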

Other observations

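Part of the genes raised in both F4 and G2 were lower in the knock-out than in MF. Off chromosomes 1 and 6 there were 171 such genes, with a median log2 fold change against MF of 1.31 in D11 and -1.31 in D12. This set, like that of genes lower in both F4 and G2, rests on the G2 calls, which fell from 434 to 2 without G2 p4-2. By the edgeR test 57 of the 171 were called lower in D12 than in MF and 6 higher, against 1012 of 13994 other genes lower (33.3 and 7.2%). D12 was lower than D11 for 150, which a rise in D11 alone would give. D11 carries wild-type Msl2, so a rise found in D11 as well does not belong to the swapped domains alone.

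The criteria for the genes lower in both F4 and G2 than in MF were written before the test. There were 51 off chromosomes 1 and 6, 8 of them X-linked, with medians of -0.67 in F4 and -0.60 in G2. Of these, 31.4% were lower in D12 than in D11 (16 lower and 12 higher), against 16.6% of 14114 other genes (two-sided Fisher exact p = 0.00803). Off chromosomes 1 and 6, 1781 genes in all were called higher in D12 than in D11. Whether higher calls were also more frequent among the 51 was not tested, so the Fisher result alone does not show a shared direction. Against MF, 22 of the 51 were called lower in D12 and 2 higher, but the MF libraries had also taken part in choosing these genes. The criterion for a change shared with loss of Msl2 asked for a majority lower in D12 than in D11, so this stayed open. Chance high values in the MF libraries also stayed open, because the median in D11 was -0.34, which narrowly missed the bound of 0.5 times that of F4. The Fisher test was tried as the deciding value for this explanation after that result was seen and was not kept.

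Other splits of the libraries were set beside the lines, each fitted on the lines compared. For D12 against MF the lines gave 3202 genes and the highest other split 13, with 1 of 35 splits as large. This met the criterion against an arbitrary split of these libraries. For F4 against MF they gave 1333 and 48, with 1 of 35, and for D12 against D11 4081 and 0, with 1 of 35, so the criterion was met for these as well. A share of 1 of 35 is the smallest these designs allow and was not adjusted over the 8 comparisons. It cannot address chance between clones, as each genotype is a single line. For D11 against MF they gave 324 against 416, with 2 of 35 as large, and for G2 against MF 211 against 325, with 2 of 35, and chance was not excluded. For F4 against D11 they gave 0 against 5274, with 35 of 35 as large, for G2 against D11 0 against 1747, with 10 of 10, and for G2 against F4 0 against 3418, with 35 of 35. In the edgeR fit of all lines these 3 comparisons had 3113, 1603 and 576 genes at an unadjusted p under 0.05, and the DESeq2 Wald test called 576, 125 and 1. The large counts of other splits point to a structure among the libraries, and the split by passage gave 1238 for F4 against D11 and 3202 for G2 against F4.

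For the number of chromosomes called, the lines gave 1 in D12 with a highest other of 1 (17 of 35 splits as large), 2 in D11 with 3 (5 of 35), 1 in F4 with 3 (20 of 35) and 2 in G2 with 5 (8 of 35). For gene lists they gave 11 in D12 with 11 (2 of 35), 7 in D11 with 10 (10 of 35), 8 in F4 with 10 (8 of 35) and 5 in G2 with 10 (18 of 35). Chance was not excluded for the number of lists in any line. A number of 1 or 2 chromosomes cannot separate groupings and says nothing about the shift itself. Library by library, the median of chromosome 6 was 0.41 to 0.44 in the 4 D12 libraries and at most 0.0195 in MF, and that of chromosome 1 was 0.40 to 0.52 in the 4 F4 libraries, 0.33 to 0.60 in the 3 D11 libraries, 0.17 to 0.49 in the 3 G2 libraries and at most 0.0242 in MF.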
